A study of Zea mays subsp. mays with 2 samples.

How the data were processed

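Chromatin immunoprecipitation followed by sequencing was carried out on maize endosperm 15 days after pollination with a custom rabbit antibody raised against full-length Opaque11 (O11), a basic helix-loop-helix transcription factor of the endosperm. There were 2 libraries, 1 from wild type kernels and 1 from homozygous o11 mutant kernels. The mutant kernels lack the O11 protein, per the labels, and served as the negative control.

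The authors deposited a single list of peaks for the series and a matching list of summits. Bowtie2 and MACS2 version 2.0.10 are named in the submitters' processing notes, without their settings. The peak names hold the tags v3 and q0.01, and the lowest −log10 q in the list was 2.17. The genome build is not given in the sources used here, so coordinates are printed as the files give them, counted from 1 and without a build name. The labels describe the mutant library as the negative control, and the values are read in that way here, as wild type over mutant. No column of the files names a library.

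Per the file headers, each peak carries a pileup at its summit (a read coverage signal), a fold enrichment (a linear ratio), a −log10 p-value and a −log10 q-value. All 9080 summits had the name, position and −log10 q of their peak, and the peak names were numbered without a gap. The authors' fold enrichment was taken as the pileup plus 1 over the local background plus 1. The local background that this implies was solved for each peak, and the upper Poisson tail of the pileup over that background differed from the authors' −log10 p by at most 0.000209. The background had a lower limit of 1.06 reads, shared by 3150 peaks (34.7%, tolerance 0.001). This limit equals 4.21 reads per kb of a window of 251 bp, the length of the shortest peak. Above the limit, the commonest background values were spaced by 0.879 reads, read here as what 1 control read was worth after scaling. Read totals of the libraries are not in the peak list, so the depth of each library is unknown. Pileups are whole numbers from 7 to 453, and intervals on them are exact Poisson intervals at the 95% level. Shares of peaks carry Wilson 95% intervals. Both cover counting error only, and reads from PCR-amplified libraries without molecular identifiers are not independent molecules.

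With 1 library per genotype there is no replicate check of any difference between wild type and mutant. The p and q values are the peak caller's, compare these 2 libraries, and say nothing of the spread between kernels or immunoprecipitations. Tests run here compare peaks or positions within the list, which are not replicates.

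Peaks per Mb were computed for chromosomes 1 to 10 over the length up to the end of the last peak, since chromosome lengths of the build were not used here. Their evenness was tested with a chi-square test, and each chromosome has an exact Poisson interval. Each chromosome was also divided into 5 equal parts of that length and compared with an even 20% by an exact binomial test. Grouping was measured as the share of summits with another summit within 10 kb on the same chromosome, against 1000 sets of random positions drawn between the first and last summit of each chromosome, in a one-sided permutation test. The share of strong sites with a neighbour was compared with that of the rest in a permutation test with 100000 permutations. Windows of 5 Mb were used for maps. A window was called a low-background window where it held at least 10 peaks with a pileup under 20 and at least 50% of those lay at the lower limit of the background.

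The peaks named in the text are the 10 with the largest fold enrichment, a rule fixed before the data were examined. The alternatives fixed at the same time were the peaks at or above the median −log10 q, the peaks with a fold of at least 5, and 5 kb in place of 10 kb. The division of the chromosomes into 5 parts and the low-background windows were chosen after seeing the data, as were these alternatives: peaks with a pileup of at least 20, a raised background, random sets that keep the number of summits per 1 Mb, and other window sizes.

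The clustering test was tested on simulated positions. Uniform positions for the 8967 chromosomal peaks gave a mean ratio of 0.999 to the random sets, and with 40% of positions placed in planted pairs 44.3% were found near another, which includes chance neighbours. The uniform positions and the random sets were drawn in the same way, so the first value checks the computation and not the effect of uneven density. A simulated background recovered from rounded folds was off by at most 7.03e-05 in 5000 peaks. The same formula made and inverted those folds, so this checks the rounding and not the formula.

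Motif, transcription start site, gene list and product class results had been planned, on condition that a genome and annotation of the build of the peaks was at hand. The reference table held gene names of another maize assembly and no sequence, so these results were not made, and peaks are given by position without gene names. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.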

Results

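To locate the DNA bound by O11 in the filling endosperm, chromatin from wild type kernels at 15 days after pollination was precipitated with an anti-O11 antibody, and chromatin from o11 mutant kernels was precipitated in the same way as the background. O11 is the product of Opaque11, a basic helix-loop-helix transcription factor gene whose loss gives small, opaque kernels. Each genotype had 1 library, so no value below carries a replicate error. The values per peak are those of the authors' deposited list. Total read numbers are not part of it.

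Wild type chromatin was enriched over o11 mutant chromatin at 9080 places in the list. Of these peaks, 8967 (98.8%, 95% interval 98.5 to 99.0%) lay on chromosomes 1 to 10. The mitochondrial sequence held 89 peaks, the plastid sequence held 4, and 13 unplaced scaffolds held 20. The median peak was 354 bp long, with quartiles of 283 and 480 bp, and the longest, on the mitochondrial sequence, reached 3285 bp. The median pileup at the summit was 16 reads, with quartiles of 12 and 23.

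Most sites were enriched by a moderate factor and few by a large one. The median fold enrichment was 5.84, with quartiles of 4.87 and 7.70. A fold of at least 5 was reached by 6661 peaks (73.4%), of at least 10 by 1047 (11.5%), of at least 20 by 51 (0.562%) and of at least 30 by 8. On the chromosomes, longer peaks had larger folds across peaks (Spearman's rho 0.49, Pearson's r 0.49) and larger pileups (rho 0.45, r 0.20). Pileup also went with fold (rho 0.58, r 0.32) and with background (rho 0.63, r 0.85). The fold is computed from the pileup, each peak had to exceed its background, and a peak's length is the stretch over the caller's threshold, so these 4 relations are in part built into the list and no p-value is given for them. Peaks are not independent replicates.

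**Figure D1:**
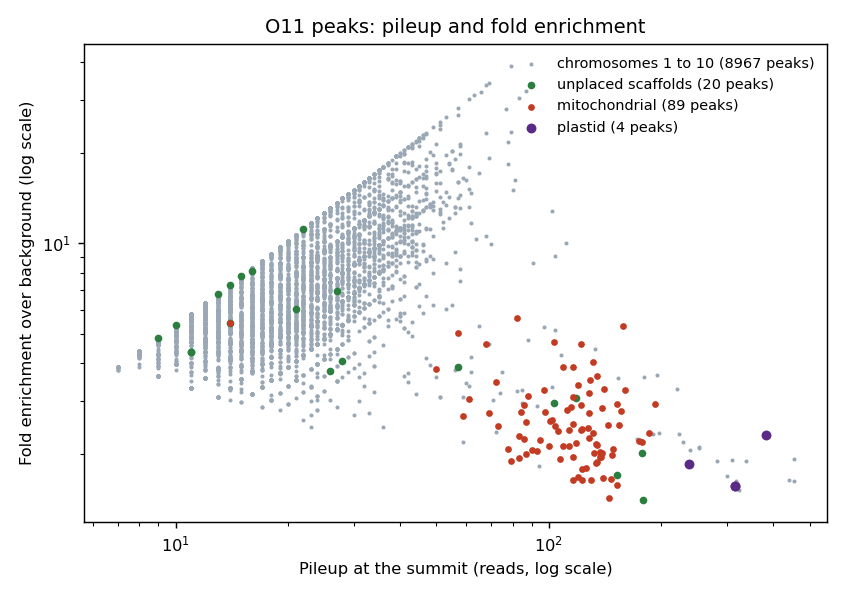
Fold enrichment (vertical, log scale) against pileup at the summit in reads (horizontal, log scale) for each of the 9080 peaks, coloured by the sequence they lie on. The straight upper edge holds the peaks at the lower limit of the background, 1.06 reads. The 4 plastid peaks and most of the 89 mitochondrial peaks lie at high pileup and low fold.

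The site with the largest fold enrichment lay on chromosome 6, from 165099861 to 165100427. Its summit at 165100149 had a pileup of 79 reads (95% interval 62.5 to 98.5) over a background of 1.06 reads, a fold of 38.9 and a −log10 q of 108.1. Chromosome 6 held 4 of the 10 sites with the largest fold, called the strongest here. The other three had summits at 96483898 (fold 33.5, pileup 68), 156591182 (fold 31.1, pileup 63) and 106213557 (fold 30.1, pileup 61). The site at 156591182 was 1501 bp long, and a second site with a fold of 24.7 had its summit 2285 bp away. Chromosome 10 held the site next to the top, from 146402092 to 146403073, with a fold of 34.0 and a pileup of 69 reads (53.7 to 87.3).

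Chromosomes 2 and 3 each held 2 of the 10. On chromosome 3 the summit at 174803193 had a pileup of 87 reads, the highest of the 10, over a background of 1.74 reads, and a fold of 32.1. The summit at 1600367 on the same chromosome had a pileup of 83 reads and a fold of 30.5. On chromosome 2 the summit at 189061455 had a fold of 31.9, and a further site with a fold of 20.9 lay 2457 bp away. The summit at 185404614 had a fold of 28.0 and a neighbour of fold 5.82 at 1017 bp. Chromosome 1 held 1 of the 10, at 261033670, with a fold of 28.2 and a pileup of 57 reads (43.2 to 73.9). The pileups of these sites ran from 57 to 87 reads. The ranking is by fold, so a low background raises a site in it. In 6 of the 10 the background was at its lower limit, and 9 of the 10 lay in low-background windows (at least 50% of the peaks with a pileup under 20 at that limit), which held 39.2% of the chromosomal peaks.

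Chromosome 8 had the highest density of sites, 6.27 per Mb (95% interval 5.91 to 6.66), and chromosome 4 the lowest, 2.47 per Mb (2.27 to 2.67), a ratio of 2.54. Chromosome 2 followed with 5.71 per Mb, chromosome 6 with 5.60 and chromosome 9 with 5.23. Chromosomes 1, 3 and 5 had 4.14, 4.11 and 4.16 per Mb. Chromosome 7 had 3.34 and chromosome 10 had 3.06. The density over all of them was 4.36 per Mb, and a chi-square test rejected an even spread (chi-square 638.7, 9 degrees of freedom, p = 1.02e-131). Among the 3112 peaks with a pileup of at least 20 the densities ranged only from 1.14 per Mb on chromosome 10 to 1.81 on chromosome 8 (chi-square 58.3, p = 2.88e-09), and chromosome 8 over chromosome 4 was 1.50. Both chi-square tests and the intervals treat sites as independent, which neighbouring sites are not. The p-values are therefore too small and the intervals too narrow by an unknown amount. The share of peaks at the lower limit of the background also differed. It was 42.9% on chromosome 8, 51.9% on chromosome 2, 48.2% on chromosome 6 and 44.3% on chromosome 9, the 4 densest. It was 15.6% on chromosome 5, 29.3% on chromosome 1, 32.3% on chromosome 3, 21.7% on chromosome 7, 29.0% on chromosome 10 and 12.7% on chromosome 4.

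Sites were fewest in the second and middle of 5 equal parts of the chromosomes and most frequent in the last, at the higher coordinates. The second part held 914 sites (10.2%, 95% interval 9.58 to 10.8%) and the middle part 1066 (11.9%, 11.2 to 12.6%), against 20% for an even spread (exact binomial p = 6.63e-139 and 1.33e-92). The middle part held under 20% of the sites on 10 of 10 chromosomes. The last part held 3267 sites (36.4%, 35.4 to 37.4%), and none of the chromosomes had under 20% of its sites there. The first part held 1694 (18.9%), and the fourth held 2026 (22.6%, 21.7 to 23.5%, exact binomial p = 1.46e-09). Peaks with a pileup of at least 20 had 21.3% of their number in the first part, 11.7% in the second, 11.5% in the middle, 24.0% in the fourth and 31.4% in the last. The tests treat sites as independent, which neighbouring sites are not.

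In windows of 5 Mb the median number of sites was 16, with quartiles of 9 and 29.2, over 416 windows. The fullest window was 135 to 140 Mb on chromosome 8, with 114 sites. Next came 150 to 155 Mb on chromosome 9 with 102, 130 to 135 Mb on chromosome 8 with 99, and 155 to 160 Mb on chromosome 8 and 145 to 150 Mb on chromosome 6 with 98 each. Of the 114 sites in the fullest window, 75.4% lay at the lower limit of the background, and 11 had a pileup of at least 20. The fullest single Mb was 154 to 155 Mb on chromosome 9, with 58 sites, a median fold of 5.83 and a highest fold of 18.5.

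**Figure D2:**
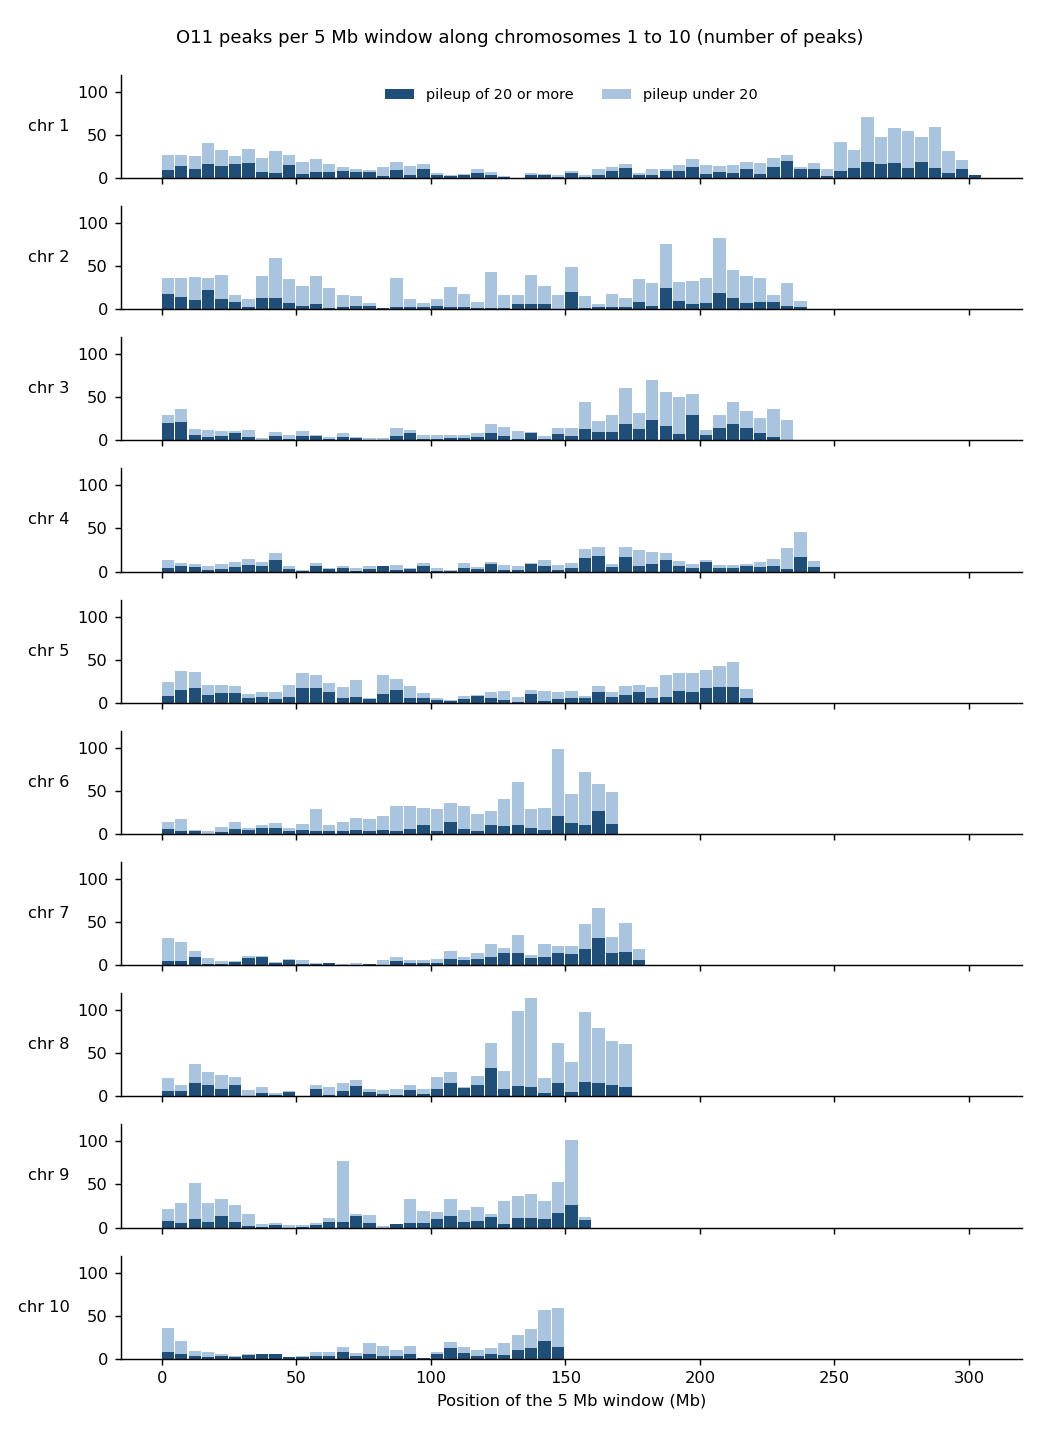
Number of peaks (vertical) in each 5 Mb window along chromosomes 1 to 10 (horizontal, Mb), split into peaks with a pileup of at least 20 reads (dark) and under 20 (light). The fullest window, 135 to 140 Mb on chromosome 8, holds 114 peaks, of which 11 have a pileup of at least 20.

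Sites lay close to one another more often than random positions do. Of the 8967 chromosomal summits, 3710 (41.4%, 95% interval 40.4 to 42.4%) had another summit within 10 kb. Random sets gave 8.91% on average and 10.2% at most, a ratio of 4.65 (one-sided permutation p = 0.001, the smallest that 1000 sets can give). Against random sets that keep the number of summits in each 1 Mb the ratio was 2.62, with the same p. There were 987 pairs and 453 runs of 3 or more summits, which held 1736 peaks, and 5257 summits stood alone. The largest run was on chromosome 2 from 153373735 to 153422717, with 19 peaks in 49.0 kb and a median fold of 5.46. A run of 13 peaks lay next to it, from 153330393 to 153361477, with a median fold of 4.21. A run of 10 peaks lay from 185870899 to 185894570 on the same chromosome, with a highest fold of 16.0, and all of its peaks had a background at the lower limit.

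Strong sites were not shown to differ from the rest in this respect. Of the 1046 chromosomal peaks with a fold of at least 10, 452 (43.2%, 40.2 to 46.2%) had a neighbour within 10 kb. Of the other 7921, 3258 did (41.1%, 40.1 to 42.2%). The difference of 2.08 percentage points had a two-sided permutation p of 0.204.

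**Figure D3:**
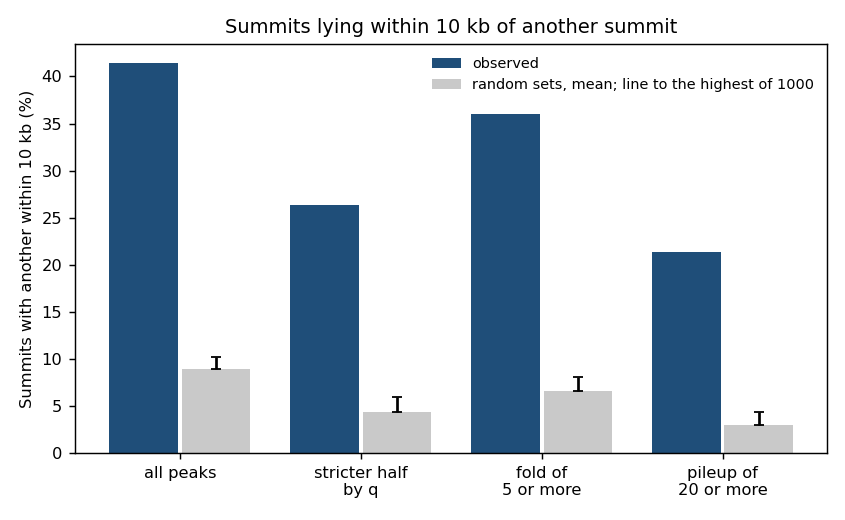
Share of summits with another summit within 10 kb (vertical, percent) for all chromosomal peaks and for 3 stricter lists, beside the mean of 1000 random sets with a line to the highest set. The observed share is 41.4% against 8.91% for all peaks and 21.3% against 3.05% for peaks with a pileup of at least 20.

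Most organelle peaks had a higher pileup and a lower fold than the median chromosomal peak. The 89 mitochondrial peaks had a median fold of 2.43 (quartiles 2.04 and 2.92, highest 5.66), against 5.90 (4.95 and 7.75) on the chromosomes. Their median pileup was 120 reads over a median background of 45.7 reads, against 16 over 1.54 on the chromosomes. They covered 53.6 kb of a sequence whose last peak ended at 561.4 kb, a density of 15.9 per 100 kb against 0.436 on the chromosomes. The 4 plastid peaks had folds from 1.56 to 2.30. On the chromosomes, 34 peaks had a background of at least 20 reads and a median fold of 2.28. Among them, 5 lay between 234545520 and 234728256 on chromosome 1, with pileups of 253 to 453 reads and folds of 1.57 to 2.09. A further 5 lay between 172415297 and 172440340 on chromosome 4, with pileups of 301 to 453 reads and folds of 1.51 to 1.92.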

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

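Peaks outside the chromosomes drew attention because a nuclear transcription factor was precipitated. The list held 89 peaks on the mitochondrial sequence, 4 on the plastid sequence and 20 on unplaced scaffolds. Such counts decide little where DNA is present in many copies, and unplaced scaffolds can be nuclear sequence. The tests in this part were chosen after the values had been seen.

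For the mitochondrial peaks, 0 of the 89 reached the chromosomal median fold of 5.90, and 4 reached the lower quartile. The first count does not decide whether they are sites like those on the chromosomes, since 0 of the 34 chromosomal peaks with a background of at least 20 reads reached it either, with a highest fold of 4.47 against 5.66 for the mitochondrial peaks. Small excesses passing a Poisson test on DNA present in many copies are a candidate explanation. Those 34 peaks had a median fold of 2.28, beside 2.43 for the mitochondrial peaks, but a set picked by its background tends to low folds, so this value does not decide either. O11 association with mitochondrial sequence, and a different mitochondrial share of the 2 chromatin preparations, stay open as well.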

How the results depend on the processing

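The clustering and the share of the middle of each chromosome kept their direction and their side of the threshold under the alternatives run for them. So did the density of chromosome 8 over chromosome 4. The order of the other chromosomes did not hold. Among peaks with a pileup of at least 20, chromosomes 2 (1.39 per Mb) and 6 (1.44) fell below the density over all chromosomes (1.51). Chromosomes 5 (1.77) and 1 (1.68) rose above it, and chromosome 10 (1.14) was the sparsest in place of chromosome 4 (1.21). The number of peaks was 9080 as deposited, 4544 at or above the median −log10 q (by construction), 6661 at a fold of at least 5 and 8814 with a raised background. The raise set every background to at least 1.76 reads, the median over peaks in windows that were not low-background but held at least 10 peaks with a pileup under 20. That raise moved the median fold from 5.84 to 5.27, and 8 of the 10 strongest peaks were still among the 10 strongest. The stricter lists keep those 10 by construction. After the raise the chromosome 6 site at 165100149 (pileup 79) was no longer first by fold. The chromosome 3 summit at 174803193 has a larger pileup (87) and then the same background. The density of chromosome 8 over chromosome 4 was 2.54 and ranged from 1.50 (pileup of at least 20) to 2.55 (fold of at least 5). Clustering ratios at 10 kb against random positions over the whole chromosome ranged from 4.65 to 7.01, and the ratio at 5 kb was 7.27. Against sets that keep the number per 1 Mb the ratio was 2.62, and 2.47 with summits under 1 kb apart thinned. The middle of 5 equal parts of the chromosomes held 10.6 to 11.9% of the sites. The ratio of peaks with a pileup of at least 20 inside over outside the low-background windows was 0.762 in 5 Mb windows (95% interval 0.637 to 0.898) and 0.708 in 2 Mb windows (0.590 to 0.867). It no longer excluded 1 in 10 Mb windows (0.911, 0.752 to 1.09) or with the pileup limit at 30 (0.902, 0.730 to 1.11). The cause of these moves was not tested. The raised background, the pileup limits, the window sizes and the sets that keep the number per 1 Mb were chosen after seeing the data, as were the division into 5 parts with its alternatives, the low-background windows and the alternative for the 10 strongest peaks. The planned motif, transcription start site, gene list, product class and gene number alternatives were not run, for want of a genome of the same build. No paired analysis was possible because each genotype had 1 library. The lowest pileup in the list was 7 reads, and how the list depends on depth was not tested.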

Other observations

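The background of the peaks changed in long stretches of chromosome. On chromosome 8, 10.8% of the 213 peaks from 80 to 130 Mb lay at the lower limit of the background (95% interval 7.30 to 15.7%), against 65.0% of the 638 peaks from 130 to 175 Mb (61.3 to 68.6%). The density of peaks was 4.26 per Mb in the first stretch and 14.2 in the other, and the median pileup 19 and 12 reads. Density was already 9.10 per Mb from 120 to 130 Mb, where 9.89% of peaks lay at the limit, and 21.3 per Mb from 130 to 140 Mb, where 68.1% did. Further stretches of at least 3 low-background windows in a row were 275 to 295 Mb on chromosome 1, 35 to 75, 135 to 150 and 175 to 195 Mb on chromosome 2, 170 to 195 Mb on chromosome 3, 85 to 120 and 125 to 160 Mb on chromosome 6 and 20 to 35 Mb on chromosome 9. Chromosome 4 had 0 such windows of the 7 with enough peaks and chromosome 5 had 1 of 25, against 26 of 38 on chromosome 2. Over peaks at least 100 kb apart, 66.0% of 8949 pairs were alike in whether the background was at its limit. In 1000 shuffles among peaks of equal pileup across all chromosomes the share was 57.3% on average and 59.1% at most. The one-sided permutation p was 0.001, the smallest they can give. Since the shuffles crossed chromosomes, differences between whole chromosomes also raise the observed share above them. The test thus does not isolate stretches within a chromosome.

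The tests of this pattern were chosen after it had been seen. The share of weak peaks at the limit in the last of 5 equal parts differed by 52.2 percentage points between chromosome 8 (70.2%) and chromosome 5 (18.1%). This argues against a like share at the far end of every chromosome. The last part was not compared with the rest of the same chromosome, so a rise toward the ends stays open. Every background was raised to at least 1.76 reads, the median over peaks in the other windows with at least 10 weak peaks. The raise removed 5.97% of the 3518 peaks inside the low-background windows and 1.03% of all 5449 other chromosomal peaks. Most peaks inside thus did not need a background below 1.76 reads to pass. The shares are of all peaks, not of the extra weak ones, and the raise was to a median of called peaks. How far the low limit accounts for the extra weak peaks is therefore not decided. For density, the 87 low-background windows were compared with the 112 other windows that held at least 10 weak peaks, of 416 windows in all. Sparser windows were left out, so the ratios are not against the rest of the chromosomes. The low-background windows held 1.68 times as many peaks with a pileup under 20 per window (bootstrap 95% interval 1.45 to 1.93). They held 0.762 times as many with a pileup of at least 20 (0.637 to 0.898). The second interval lay below the first in all 4 settings of window and pileup limit. It included 1 in 10 Mb windows and with the pileup limit at 30. The bootstrap took single windows as independent, while low-background windows often lay in a row, so its intervals are likely too narrow. Whether O11 sites are denser there stays open, since the windows were chosen on their weak peaks and the list does not separate extra weak peaks from a lower pileup at every site (medians of 13 reads inside and 18 outside). Peaks with a pileup of at least 20, not used to choose the windows, lay at the limit in 30.9% of cases inside and 10.1% in the comparison windows. The difference was 20.8 points (16.4 to 25.4). The windows pool all chromosomes, so differences between whole chromosomes also raise it, and it does not isolate stretches within a chromosome. Nor does it show what caused the state. Different haplotypes in the mutant and wild type kernels, with fewer mutant reads mapping, may be one source, and testing that needs the reads.

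The close spacing of sites was weighed against technical explanations written down before their tests were run. Uneven density at a scale of 1 Mb or more as the whole cause is argued against by the ratio of 2.62 to sets that keep the number of summits per 1 Mb. Those sets spread summits evenly within each 1 Mb, so unevenness at a finer scale was not tested. Dropping the weaker of any 2 summits under 1 kb apart removed 428 summits and left a ratio of 2.47. This argues against the splitting of 1 site by the peak caller at under 1 kb as the whole cause. Splitting of broader sites into summits further apart was not tested. Repeated sequence and the spacing of genes stay open, since no genome was used here. No biological explanation was tested.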
